A study of Mus musculus with 7 samples.

How the data were processed

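Messenger RNA was measured by sequencing in 7 libraries of cultured mouse haematopoietic stem and progenitor cells (HSPCs). Per the labels, 3 libraries came from cells overexpressing MN1, 3 from cells overexpressing MN1-∆pQ (written MN1-dpQ here) and 1 from untransduced cells. The groups and the replicate numbers were taken from the sample titles. The series text calls the samples of each transduced group independent, and no source used here says whether they came from separate animals, so the p-values measure the spread between these samples. Per the labels' protocols, cells were transduced and sorted, kept for 7 to 9 days in medium with IL-3, IL-6 and stem cell factor, and RNA was selected for poly(A) and read from both ends at 150 bases. The labels do not say which library was taken on which day, and no strand setting is given in the sources used here.

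The authors deposited 1 table of estimated counts per gene symbol for all 7 libraries, not normalised. Per the submitters' processing notes, kallisto, DESeq2 and the GRCm38 genome build were used; the versions and the transcript index are not given in the sources used here. The table had 34305 rows, and 32.5% of its values were not whole (tolerance 1e-06). Every sample column was used. In 26 rows the gene symbol had been turned into a calendar date, and 2 of these symbols occurred in a pair of rows. These rows held 0.172% of all counts, stayed in the tests and are not named.

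Counts were rounded to whole numbers. Totals ran from 38210660 to 67728658 per library. Genes were filtered with edgeR's filterByExpr on the 2 transduced groups, which left 14808 genes, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of 3 MN1 against 3 MN1-dpQ libraries with group as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is given as log2 of MN1 over MN1-dpQ with its standard error. CPM values were scaled by TMM over all 7 libraries and are given as mean ± SD over 3 libraries. The untransduced group has 1 library, so it was kept out of the tests. It was described by log2 CPM differences (prior count of 2), and list medians were set against 10000 random lists matched on mean expression in 20 bins.

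A set of 30 lists of genes, 17 of pathways or complexes and 13 of cell type markers, were fixed before the data were examined, as were the tests, most alternatives and the rule for naming genes. Lists with at least 5 tested genes (29 lists) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list and fry were run as alternatives. Of 593 list entries, 2 matched no symbol of the table and were not analysed here. A count "adjusted over the list alone" uses Benjamini-Hochberg within that list.

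The rule named Mn1 first. It then named the 10 genes with the largest fold change in each direction among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. From each list it took up to 4 passing genes with the largest absolute fold change, or the most abundant gene where none passed. It added Hoxa9, Hoxa10, Meis1, Mecom, Flt3, Kit, Cd34, Cebpa, Irf8, Mpo and Csf1r whatever their values. For the untransduced library it took the 5 genes with the largest difference in each direction from each transduced group, among genes with at least 100 counts in that library or in every library of the group. Of the genes chosen by this rule, 1 is not reported here. Numbered predicted genes, Rik clones, accession-like names and processed pseudogenes were left out. Coordinates come from GENCODE M21 on GRCm38, matched by symbol. Genes with close copies, such as the Ear, Mcpt, Ifit, Tgtp and Hbb families and Csf2rb with Csf2rb2, can share reads, so their separate levels are uncertain. Overlapping and antisense genes cannot be told apart without a stated strand.

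Replicates were checked for being distinct. The chi-square per gene between replicates of a group lay between 44.0 and 355, far above sampling noise. The replicate numbers were checked for pairing. Deviations from the group means correlated at 0.367, 0.258 and 0.320 across genes between libraries of the same number and between -0.282 and -0.0599 for different numbers. All same-number values exceeded 0.1, so the numbers were taken to pair the libraries from the data, since the labels do not say what a number marks. A fit with the replicate number as a block was therefore run beside the main one.

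The pipeline was tested on simulated counts drawn from the real means, dispersions and library sizes for MN1 against MN1-dpQ, with 14581 genes tested. Without the block it recovered 29.0% of 100 genes changed by a log2 of 1 and 93.0% of 100 genes changed by a log2 of 2, with 4.69% false calls. With the block these shares were 23.0% and 88.0%, with 8.26% false calls. Null data gave 0 calls. The counts were drawn separately for each gene and library, with no effect of the replicate number and no library standing apart. The changed genes had means above 5 CPM. These shares therefore do not rank the fits with and without the block for the real data, nor cover genes at lower levels.

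Alternatives were the replicate block, RLE size factors, library totals alone, no filter, a stricter filter (at least 1 CPM in 3 libraries and 50 counts in sum), all 7 libraries in the fit, each transduced library left out, DESeq2 1.42.0 with and without the block, limma-voom, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. A fit without the replicate 2 pair, 2 list tests with the block and the untransduced library's side among genes called with the block were added after seeing the data.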

Results

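The libraries measured poly(A) RNA of mouse HSPCs, a mixed population of blood-forming stem and progenitor cells, after forced expression of MN1 or of MN1-dpQ. MN1 is a transcriptional co-regulator that acts as an oncogene in acute myeloid leukaemia, and MN1-dpQ is the protein without its polyglutamine stretch. The main comparison, 3 MN1 against 3 MN1-dpQ libraries, asks which parts of the expression state of MN1 cells differ when that stretch is missing. A single library of untransduced cells gives the background. Totals were 38210660, 40310501 and 43194988 counts for MN1 replicates 1 to 3, 67728658, 49185227 and 43025153 for MN1-dpQ replicates 1 to 3 and 38642911 for the untransduced library.

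Mn1 itself (chromosome 5, 111417362 to 111457033 on GRCm38, plus strand, protein coding) was counted far above the untransduced level in every transduced library. It stood at 314, 287 and 288 CPM in the MN1 libraries, at 691, 404 and 728 CPM in the MN1-dpQ libraries and at 33.6 CPM without transduction. The mean was 297 ± 15.1 CPM (SD, n = 3) in MN1 and 607 ± 177 CPM (SD, n = 3) in MN1-dpQ. Mn1 was thus lower in MN1, with a log2 fold change of -1.05 (SE 0.23, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0282). With single libraries left out Mn1 kept this call in 1 of 6 fits, the one without MN1-dpQ replicate 2, at log2 fold changes from -1.25 to -0.89 and edgeR Benjamini-Hochberg adjusted p up to 0.104. Counts of the construct and of the endogenous gene cannot be separated in a table per symbol, and the species of the construct is not given in the sources used here. The groups differed in Mn1 counts as well as in the polyglutamine stretch, and the main comparison cannot tell these apart.

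MN1 cells had higher levels of HOXA cluster genes, of the HOX cofactor genes Meis1 and Meis2 and of the progenitor genes Flt3 and Cd34 than MN1-dpQ cells. Most neutrophil and eosinophil markers lay lower in MN1, as did 8 of 19 mast cell markers, with 1 higher. Of 14808 genes tested, 901 were higher and 1643 lower in MN1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 591 and 967 changed at least 2-fold. The groups did not overlap for 43.6% of tested genes, where chance gives 10% for 3 against 3. With the replicate number as a block, 2022 genes were higher and 2523 lower, and 2439 of the calls were shared in the same direction. The split depended on the scaling: library totals alone moved the median log2 fold change by 0.20 and gave 1847 higher and 1140 lower genes, or 61.8% higher against 35.4% with TMM, and all fold changes below are relative to TMM. Leaving out MN1-dpQ replicate 2, whose eosinophil, mast cell and basophil markers lay far below those of the other MN1-dpQ libraries, gave 6394 changed genes, and leaving out its whole pair, chosen after seeing the data, gave 5247. Leaving out MN1 replicate 1, 2 or 3 gave 631, 683 or 508 genes, and leaving out MN1-dpQ replicate 1 or 3 gave 506 or 941.

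**Figure D1:**
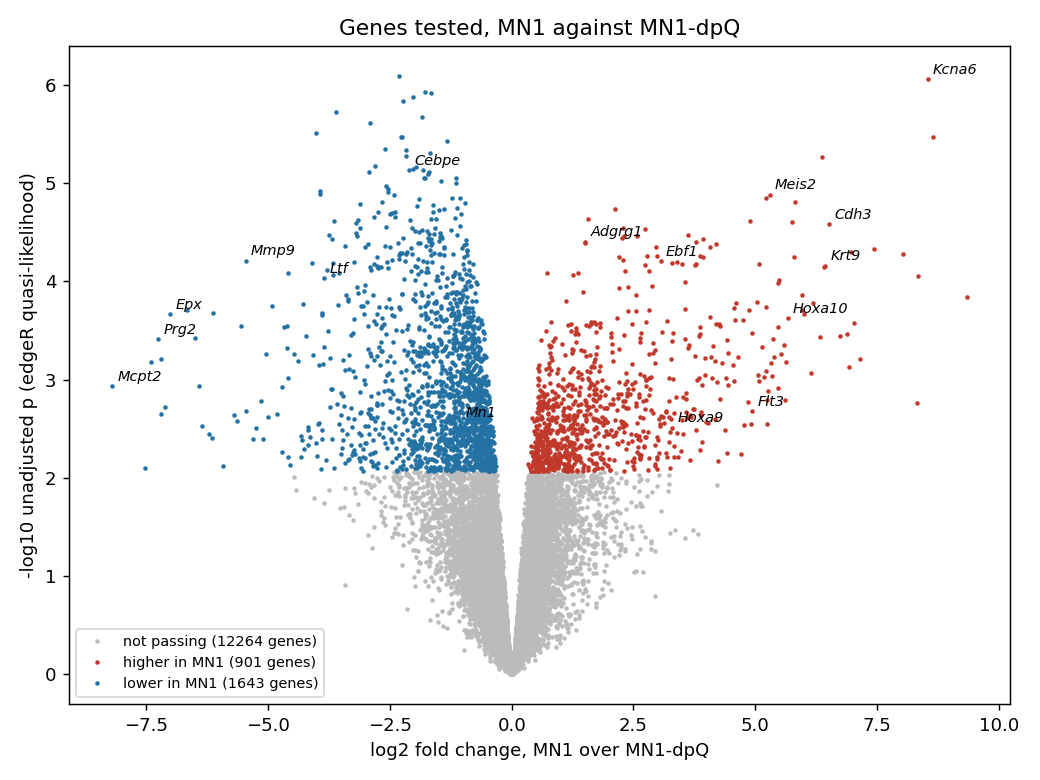
Each point is 1 of 14808 genes, with the log2 fold change of MN1 over MN1-dpQ on the horizontal axis and -log10 of the unadjusted p (edgeR quasi-likelihood test, 3 against 3 libraries) on the vertical axis. Red points are the 901 genes higher in MN1, blue points the 1643 lower and grey points those past no threshold; Mcpt2 lies farthest left of the named genes and Kcna6 farthest right.

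The HOXA cluster, which encodes homeobox transcription factors active in stem cells and in leukaemia, was higher in MN1 in 8 of 9 tested genes, and in 8 when adjusted over the list alone. Hoxa11 (chromosome 6, 52242106 to 52245810) stood at 22.5 ± 9.56 CPM in MN1 and 0.339 ± 0.350 CPM in MN1-dpQ (SD, n = 3 each), a log2 fold change of 6.01 (SE 0.84). Leave-outs of single libraries moved Hoxa11 from 5.51 to 7.03, Hoxa10 from 5.21 to 6.98 and Hoxa6 from 4.32 to 5.70, each called in 5 of 6 fits. Hoxa10 differed by 5.66 (SE 0.81), Hoxa6 by 4.75 (SE 0.68) and Hoxa9 by 3.29 (SE 0.74, 2.86 to 4.43 with single libraries left out, called in 1 of 6 fits) on the log2 scale, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p between 0.00901 and 0.0300. Hoxa3 had 189 counts over the MN1 libraries and 3 over the MN1-dpQ libraries, a ratio of 72.2 (95% exact interval 24.3 to 353, counting error only), and all 3 of the latter were in MN1-dpQ replicate 2. Camera called the cluster (adjusted p = 6.37e-10), but not with an estimated correlation (adjusted p = 0.419). In MN1-dpQ replicate 2 the HOXA genes lay above the other MN1-dpQ libraries, at a median of -0.50 against -2.32 and -2.72 relative to the mean of the transduced libraries. Hoxb4, the most abundant of 2 tested HOXB genes, did not pass (log2 fold change -0.36, edgeR Benjamini-Hochberg adjusted p = 0.438), and the HOXB list was too short for camera.

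Among 23 stem cell and leukaemia transcription factors, 6 were higher and 2 lower in MN1, and 9 and 2 when adjusted over the list alone. Meis2 rose from 0.758 ± 0.252 to 29.8 ± 13.2 CPM (SD, n = 3), a log2 fold change of 5.30 (SE 0.48, edgeR Benjamini-Hochberg adjusted p = 0.00497), while Meis1 differed by 1.27 (SE 0.27). Hlf, a regulator of stem cell quiescence, differed by 3.40 (SE 0.78) and Sox4 by 2.73 (SE 0.66). With single libraries left out Hlf ran from 2.96 to 4.69 and Sox4 from 2.36 to 3.84, each called in 1 of 6 fits. The list passed camera (adjusted p = 0.0182; adjusted p = 0.419 with an estimated correlation), and no longer did without MN1 replicate 3 (0.0542) or MN1-dpQ replicate 1 (0.0959). Of 19 HSC and multipotent progenitor markers, 7 were higher and 0 lower, and 8 when adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.419 with an estimated correlation). Cd34, a surface marker of progenitors, stood at 585 ± 61.9 CPM in MN1 and 226 ± 57.6 CPM in MN1-dpQ, and Adgrg1 at 552 ± 25.1 and 193 ± 39.5 CPM (SD, n = 3 each). Cd27 differed by 3.18 (SE 0.66, 2.75 to 4.10 with single libraries left out, called in 2 of 6 fits) on the log2 scale. Kit (-0.78, SE 0.45) and Mecom (-0.31, SE 0.53) did not pass, at edgeR Benjamini-Hochberg adjusted p = 0.244 and 0.692.

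Among genes with a mean of at least 5 CPM, the 10 with the largest rise in MN1 were Cdh3, Krt9, Hpgd, Hoxa11, Tgtp1, Adgra2, Hoxa10, Ramp3, Ddx4 and Wt1. Krt9, a keratin gene, stood at 169 ± 25.6 CPM in MN1 and 1.91 ± 1.59 CPM in MN1-dpQ, and Ramp3, a receptor-modifying protein gene, at 299 ± 66.5 and 6.06 ± 7.98 CPM (SD, n = 3 each). Cdh3, which encodes P-cadherin, differed by 6.51 (SE 0.65), Hpgd by 6.14 (SE 1.09) and Wt1, a transcription factor gene, by 5.48 (SE 1.03) on the log2 scale. With single libraries left out the log2 fold change ran from 5.64 to 8.17 for Hpgd, from 4.99 to 7.15 for Wt1 and from 5.09 to 7.58 for Ramp3, and Hpgd and Wt1 kept their calls in 3 of 6 fits and Ramp3 in 2. Kcna6, a potassium channel gene, was named by the rule for the untransduced library. It had 784 counts over the MN1 libraries and 2 over the MN1-dpQ libraries, a ratio of 449 (95% exact interval 124 to 3720, counting error only). Its transcripts hold a CAG and CAA repeat of 54 bases on the opposite strand, so reads of the construct's repeat are a limit on this value.

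Early B lymphoid genes were higher in MN1 in 4 of 10 tested members and lower in 1, with the same counts when adjusted over the list alone. Rag1 and Rag2, which cut antigen receptor genes, differed by 5.24 (SE 1.15) and 2.37 (SE 0.46) on the log2 scale, with Rag1 running from 4.61 to 7.80 and called in 1 of 6 fits with single libraries left out. Dntt differed by 3.98 (SE 0.71, 3.51 to 5.03 with single libraries left out, called in 2 of 6 fits) and Ebf1 by 3.06 (SE 0.35). All 4 stayed low, at means of 2.08 to 5.06 CPM in MN1. The list passed camera (adjusted p = 0.0170; adjusted p = 0.419 with an estimated correlation), and with library totals alone it did not (0.0562).

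Interferon-stimulated genes were higher in MN1 in 17 of 25 tested members, and in 22 when adjusted over the list alone, with 0 lower. Rtp4 stood at 24.0 ± 14.8 CPM in MN1 and 0.802 ± 0.382 CPM in MN1-dpQ, and Oasl2, an antiviral gene, at 35.2 ± 23.4 and 1.60 ± 0.908 CPM (SD, n = 3 each). Mx2 differed by 5.04 (SE 0.68) and Ifit1 by 3.90 (SE 0.73) on the log2 scale. MN1 replicate 2 was the lowest MN1 library in this group, with Rtp4 at 8.03 CPM against 26.6 and 37.3 CPM. Camera called these genes as a list (adjusted p = 1.59e-13), but not with an estimated correlation (adjusted p = 0.419). Ifit3 lost its call with the replicate block (edgeR Benjamini-Hochberg adjusted p = 0.0247 without and 0.0527 with the block).

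Neutrophil genes were lower in MN1 almost throughout. Of 21 neutrophil markers 20 were lower, also when adjusted over the list alone. Ltf, which encodes lactoferrin of the secondary granules, stood at 331 ± 168 CPM in MN1 and 4739 ± 1090 CPM in MN1-dpQ (SD, n = 3 each), a log2 fold change of -3.85 (SE 0.47). Ly6g (-5.57, SE 0.82), Mmp9 (-5.47, SE 0.63) and Retnlg (-4.60, SE 0.55) were lower by more on the log2 scale, and the 4 genes had edgeR quasi-likelihood, Benjamini-Hochberg adjusted p between 0.00554 and 0.00985. Camera called the neutrophil list (adjusted p = 1.34e-33), but not with an estimated correlation (adjusted p = 0.372). Of 15 primary granule and promyelocyte markers 3 were lower, and 3 when adjusted over the list alone, among them Fcnb (-2.31, SE 0.54) and Serpinb1a (-1.44, SE 0.25). That list passed camera (adjusted p = 0.0275; adjusted p = 0.649 with an estimated correlation), and no longer did without MN1 replicate 3 (0.0782), MN1-dpQ replicate 2 (0.607) or the replicate 2 pair (0.482). Its median log2 fold change turned to 0.14 without MN1-dpQ replicate 2, the highest library on this list, and to 0.03 without the pair. Mpo, the myeloperoxidase gene, did not pass, with a log2 fold change of -0.09 (SE 0.85). It ran from 928 to 2344 CPM in MN1 and stood at 998, 4301 and 324 CPM in MN1-dpQ, and without MN1-dpQ replicate 2 its log2 fold change turned to 1.42.

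Eosinophil markers were lower in MN1 in 8 of 10 tested members, and in 9 when adjusted over the list alone (camera adjusted p = 1.11e-07; adjusted p = 0.419 with an estimated correlation). Prg2, which encodes major basic protein, stood at 9.56 ± 2.68 CPM in MN1 and 1452 ± 1147 CPM in MN1-dpQ, and Epx, the eosinophil peroxidase gene, at 4.48 ± 0.830 and 572 ± 436 CPM (SD, n = 3 each). Ear6 (-7.40, SE 1.26), Ear1 (-7.20, SE 1.21), Alox15 (-7.19, SE 1.52), Ear2 (-6.67, SE 0.92) and Prg3 (-6.51, SE 1.01) were also among the 10 largest decreases. Of 19 mast cell markers 8 were lower and 1 higher, and 12 and 1 when adjusted over the list alone. With the replicate block 13 were lower. Mcpt2 stood at 3.95 ± 0.874 CPM in MN1 and 1156 ± 1002 CPM in MN1-dpQ (SD, n = 3 each), where replicate 2 had 26.7 CPM, and its log2 fold change was -8.21 without and -7.24 with the block, called in 2 of 6 fits with single libraries left out. Mcpt1 differed by -7.13 (SE 1.46), Fcer1a, the IgE receptor alpha chain gene, by -6.36 (SE 1.41) and Mcpt4 by -6.22 (SE 1.43). Leave-outs of single libraries moved Mcpt1 from -7.68 to -6.37, Fcer1a from -7.10 to -5.92 and Mcpt4 from -6.76 to -5.67. Each kept its call in 1 of these 6 fits. Of 12 basophil markers 4 were lower, 5 when adjusted over the list alone and 9 with the block, led by Prss34 (-4.61, SE 0.68), with Cd200r3 (-2.90, SE 0.73) and Mcpt8 (-2.15, SE 0.42). The mast cell and basophil lists passed camera (adjusted p = 0.000684 each), but not with an estimated correlation (adjusted p = 0.649 and 0.568). MN1-dpQ replicate 2 lay far below its group in all 3 lists, and inside the MN1 range on the mast cell (-0.66) and basophil (-0.43) lists, with Prg2 at 127 CPM against 2115 and 2112 CPM, and Fcer1a at 26.2 CPM against 1095 and 1156 CPM.

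**Figure D2:**
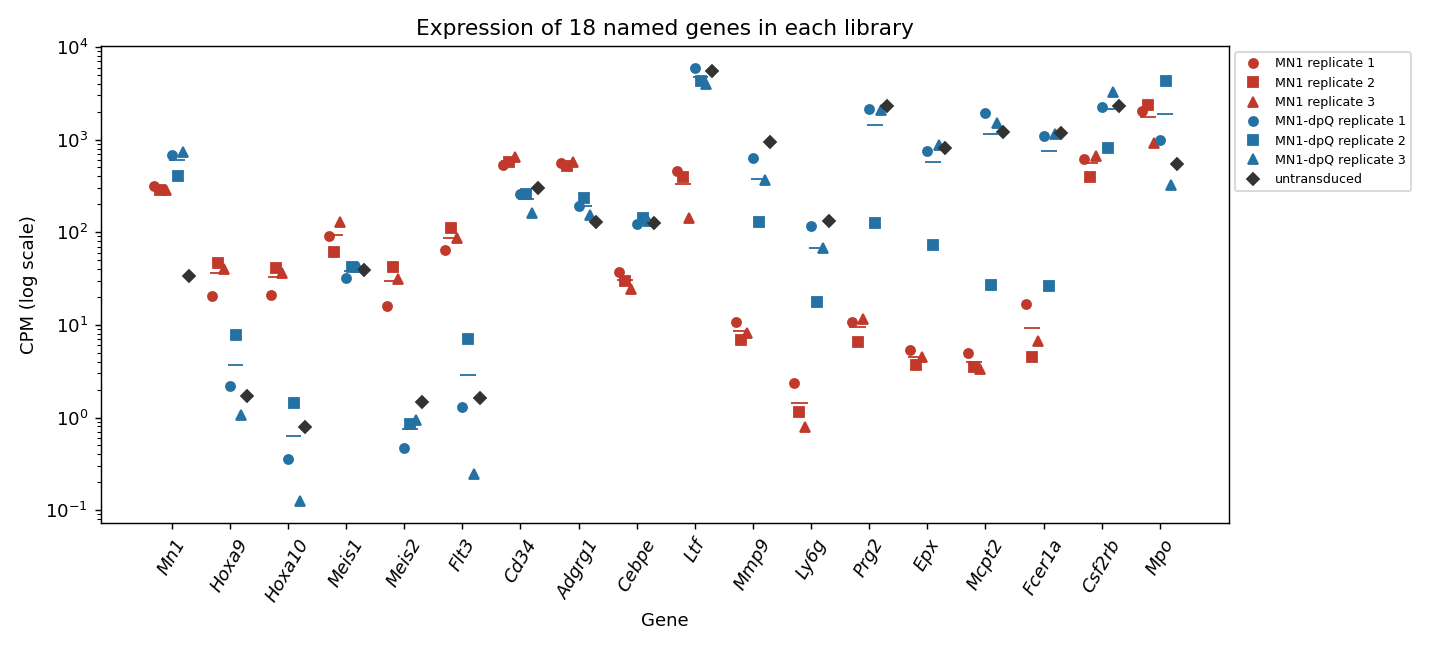
CPM on a log axis of 18 named genes in each of the 7 libraries, with red for MN1, blue for MN1-dpQ and black for untransduced cells, marker shape for the replicate number and short lines for the means of 3 libraries. Prg2, Epx, Mcpt2 and Fcer1a lie between the groups in MN1-dpQ replicate 2, and Mn1 lies at 33.6 CPM in the untransduced library.

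Monocyte and macrophage markers were lower in 9 of 26 tested members and higher in 1, with the same counts when adjusted over the list alone. The complement genes C1qa (-2.76, SE 0.56), C1qb (-2.14, SE 0.48) and C1qc (-2.03, SE 0.49) and Adgre1, which encodes F4/80 (-1.92, SE 0.42), were lower on the log2 scale. Csf1r, the M-CSF receptor gene, stood at 59.9 ± 15.2 CPM in MN1 and 109 ± 18.3 CPM in MN1-dpQ (SD, n = 3 each). The list passed camera (adjusted p = 0.000776; adjusted p = 0.534 with an estimated correlation). Lysosome and phagocytosis genes were lower in 16 of 26 members, and in 21 when adjusted over the list alone (camera adjusted p = 4.17e-08; adjusted p = 0.430 with an estimated correlation). Ctsh differed by -3.37 (SE 0.45), Tyrobp by -2.42 (SE 0.34), Cd63 by -1.70 (SE 0.44) and Ctsd, the cathepsin D gene, by -1.66 (SE 0.45). Csf1r and Ctsd lost their calls with library totals alone (edgeR Benjamini-Hochberg adjusted p = 0.0737 and 0.0546).

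Of 22 cytokine and growth factor receptor genes, 6 were lower and 1 higher in MN1, 12 and 2 when adjusted over the list alone, and 12 and 1 with the block. Flt3, a receptor of early progenitors, stood at 87.6 ± 23.4 CPM in MN1 and 2.84 ± 3.63 CPM in MN1-dpQ (SD, n = 3 each), and its log2 fold change ran from 4.41 to 6.73 with single libraries left out, called in 2 of 6 fits. The receptor chain genes Csf2rb2 (-2.76, SE 0.75), Csf2rb (-1.94, SE 0.49) and Csf2ra (-1.44, SE 0.23), whose products serve GM-CSF, IL-3 and IL-5, were lower. Csf2rb2 and Csf2rb each kept the call in 1 of 6 fits with single libraries left out, and Csf2ra in 5. MN1-dpQ replicate 2 lay inside the MN1 range on this list, at a median of -0.26 against 0.69 and 0.43 in the other MN1-dpQ libraries. The list passed camera (adjusted p = 0.00804; adjusted p = 0.419 with an estimated correlation). Of 20 myeloid differentiation transcription factors 7 were lower and 0 higher, and 7 when adjusted over the list alone (camera adjusted p = 0.00110; adjusted p = 0.377 with an estimated correlation). With the block 9 were lower and 2 higher. Cebpe, which drives late granulocyte maturation, stood at 30.7 ± 6.46 CPM in MN1 and 132 ± 10.1 CPM in MN1-dpQ (SD, n = 3 each), and Maf (-2.35, SE 0.47), Id2 (-1.76, SE 0.43) and Bhlhe40 (-1.60, SE 0.43) were lower too. Id2 and Bhlhe40 each kept the call in 1 of 6 fits with single libraries left out, Maf in 2 and Cebpe in 6. Cebpa (0.26, SE 0.34) and Irf8 (1.29, SE 0.60) did not pass in the main fit. For Irf8 the edgeR Benjamini-Hochberg adjusted p was 0.161 there, 0.0488 with the block and 0.0046 without the replicate 2 pair. Irf8 passed in 1 of 6 fits with single libraries left out, where its log2 fold change ran from 0.91 to 2.37. Without the replicate 2 pair this list missed the camera threshold (adjusted p = 0.0549).

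Ribosome biogenesis genes were higher in MN1 in 4 of 22 members, in 21 when adjusted over the list alone and in 22 with the replicate block. Ncl, which encodes nucleolin, stood at 1781 ± 281 CPM in MN1 and 1041 ± 258 CPM in MN1-dpQ (SD, n = 3 each), and Gar1 differed by 0.88 (SE 0.23), Fbl by 0.64 (SE 0.16) and Polr1a by 0.35 (SE 0.09). The list passed camera (adjusted p = 1.51e-06; adjusted p = 0.568 with an estimated correlation). None of 26 DNA replication genes passed singly or when adjusted over the list alone, while 13 were higher with the block; the list passed camera (adjusted p = 0.00594; adjusted p = 0.680 with an estimated correlation), and its most abundant gene Pcna differed by 0.14 (SE 0.12). On this list MN1-dpQ replicate 2 went against the group difference, at 0.15 against -0.32 and -0.43. On the cholesterol and megakaryocyte lists it lay inside the MN1 range, at -0.05 and -0.01. MN1-dpQ replicate 3 also lay inside that range on the cholesterol list, at 0.14. Of 28 BAF chromatin remodelling subunits 3 were higher and 1 lower, also when adjusted over the list alone, and 9 and 2 with the block. Dpf1 (2.08, SE 0.42), Dpf3 (1.28, SE 0.28) and Smarcc1 (0.85, SE 0.17) were higher and Smarca2 (-0.81, SE 0.12) lower. The BAF list passed camera (adjusted p = 0.0439; adjusted p = 0.534 with an estimated correlation), and no longer did without MN1 replicate 2 (0.0633) or MN1-dpQ replicate 1 (0.0640) or 3 (0.0863). Of 22 cholesterol biosynthesis genes 3 were higher, Dhcr7 (0.99, SE 0.25), Pmvk (0.89, SE 0.24) and Insig1 (0.69, SE 0.17), and 0 when adjusted over the list alone. That list passed camera (adjusted p = 0.0406; adjusted p = 0.729 with an estimated correlation), missed it with the block (0.0510) and ranged up to 0.257 with single libraries left out, the highest without MN1-dpQ replicate 1. Dhcr7 lost its call with the block (edgeR Benjamini-Hochberg adjusted p = 0.0601).

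Megakaryocyte markers were lower in 1 of 18 members, Rap1b (-0.55, SE 0.13, not called with library totals alone), in 0 when adjusted over the list alone and in 10 with the block (camera adjusted p = 0.0326; adjusted p = 0.725 with an estimated correlation). The megakaryocyte list missed the threshold without MN1 replicate 2 (0.265) or MN1-dpQ replicate 1 (0.0658). The other lists did not pass camera. Of 17 erythroid markers Aqp1 (1.70, SE 0.33), Rhag (1.60, SE 0.31) and Car2 (1.38, SE 0.27) were higher and Hbb-bs (-2.01, SE 0.48) lower. Of 17 dendritic cell markers 3 were higher, among them Fscn1 (2.72, SE 0.49) and Tcf4 (1.80, SE 0.39), and Itgax (-2.46, SE 0.59) was lower. Of 23 inflammatory cytokine and chemokine genes Ccl6 (-3.54, SE 0.78) and Ccl9 (-1.76, SE 0.47) were lower. Of 20 p53 target genes Fas (-1.57, SE 0.26) and Trp53inp1 (-1.30, SE 0.34) were lower and Sesn1 (0.65, SE 0.18) higher. Hk3 (-0.99, SE 0.24) was the lower gene of 19 glycolysis genes, Lck (2.48, SE 0.66, 2.10 to 3.69 with single libraries left out, called in 1 of 6 fits) the higher gene of 8 T and NK cell markers, and of 9 stromal and endothelial markers Pdgfrb (1.17, SE 0.30) was higher and Col1a1 (-2.43, SE 0.38) lower. No member passed among 22 G2/M cell cycle, 18 immediate early and heat shock and 13 mitochondrially encoded genes, whose most abundant members Mki67 (-0.29, SE 0.13), Hspa8 (0.27, SE 0.13) and mt-Co1 (-0.32, SE 0.11) gave no call. Adjusted over the list alone, 5 erythroid markers were higher and 2 lower, 4 dendritic higher and 1 lower, 1 p53 target lower, 1 T and NK cell marker higher and 1 lower, 2 stromal and endothelial markers higher and 3 lower, and 0 in the other lists. With the block, 7 inflammatory genes were lower and 3 higher, 5 p53 targets lower and 2 higher, 4 dendritic markers higher and 3 lower, 3 glycolysis genes lower, 4 erythroid markers higher and 3 lower, 1 T and NK cell marker higher and 1 lower, 1 stromal and endothelial marker higher and 2 lower, 2 immediate early and heat shock genes and 1 G2/M gene higher and 1 mitochondrially encoded gene lower. Camera adjusted p for these 10 lists lay between 0.202 and 0.957.

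**Figure D3:**
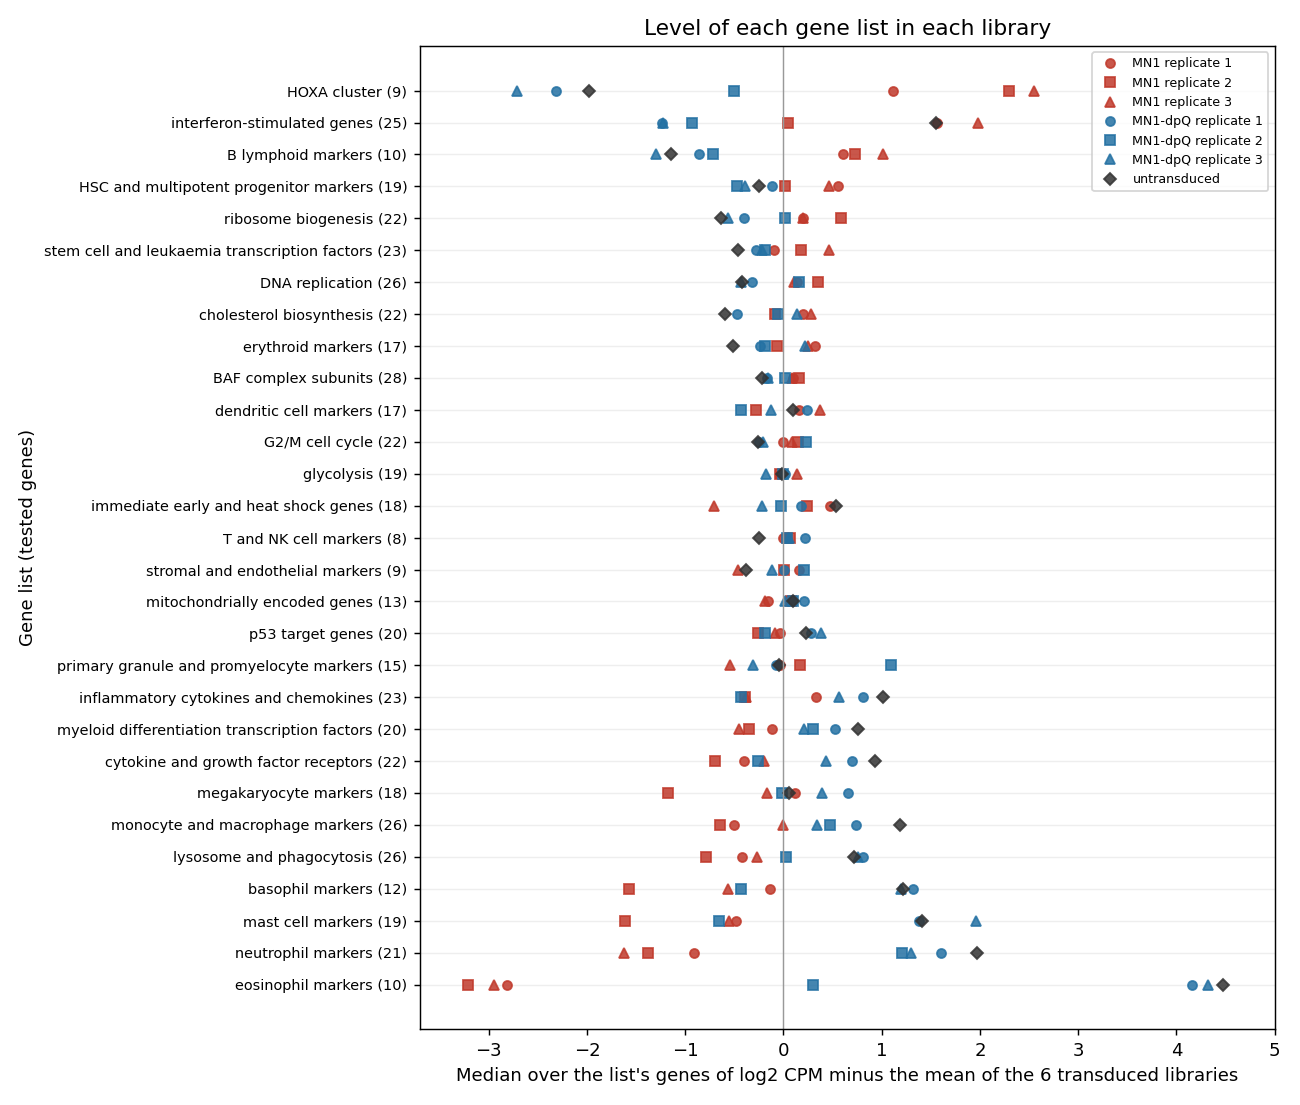
Each row is a gene list with its number of tested genes, and each point is the median over the list of log2 CPM in 1 library minus the mean of the 6 transduced libraries; red is MN1, blue MN1-dpQ and black untransduced, and shapes mark the replicate number. Eosinophil markers lie at 4.16 and 4.32 in MN1-dpQ replicates 1 and 3 but at 0.30 in replicate 2, and interferon-stimulated genes lie at 1.55 in the untransduced library, among the MN1 libraries.

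Untransduced cells resembled MN1-dpQ cells more than MN1 cells in most genes called between the transduced groups. On the primary granule, dendritic and T and NK cell lists the median difference was smaller in size from MN1 (0.13, -0.07 and 0.15). From MN1-dpQ it was -0.23, 0.25 and -0.44 on these lists. The untransduced library had most neutrophil and eosinophil markers far above the MN1 levels, with Prg2 at 2293 CPM, Mmp9 at 948 CPM and Ltf at 5488 CPM, and had low HOXA genes, with Hoxa9 at 1.73 CPM. The comparison asks on which side the background lies, and with 1 library it has no replicate check. Of the 901 genes higher in MN1 the untransduced library lay nearer MN1-dpQ in 842 (93.5%), and of the 1643 lower genes in 1586 (96.5%). It lay beyond the MN1-dpQ mean, away from MN1, in 573 and 1166 of these genes, a mean that includes the outlying MN1-dpQ replicate 2. Its log2 CPM correlated across 10340 genes, which are not independent replicates, at 0.860, 0.811 and 0.837 with the MN1 libraries and at 0.983, 0.916 and 0.969 with the MN1-dpQ libraries.

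At least 2-fold from the MN1 mean and outside the MN1 range, 1562 genes were higher and 967 lower in the untransduced library. Against MN1-dpQ these numbers were 252 and 33, and without MN1-dpQ replicate 3 the total rose from 285 to 592. The largest excesses over MN1 were those of Ear1, Mcpt2, Prg2, Ear6 and Alox15. The largest deficits were those of Myo16, Col4a1, Kcna6, Hpgd and Kcnk2. Myo16 and Kcna6 had 0 counts, and the MN1 means were at least 166-fold and 72.8-fold above the level of 3 counts in that library. Below MN1-dpQ lay Mn1, Zbed6, Top3b, Slc7a2 and Slc12a2, with Zbed6 at 1.32 CPM against 7.70 ± 1.40 CPM (SD, n = 3) and Top3b at 2.60 against 12.7 ± 6.46 CPM.

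Interferon-stimulated genes were the list in which the untransduced library left the MN1-dpQ side most. Its 5 largest excesses over MN1-dpQ were Ifit3, Ifit3b, Ifi206, Rtp4 and Ifit1, with Ifit3 at 39.2 CPM against 0.334 ± 0.231 CPM (SD, n = 3). In 24 of 25 list genes it lay above every MN1-dpQ library, with a median log2 difference of 2.75 from MN1-dpQ and 0.45 from MN1, at percentiles 100 and 99.2 among 10000 random lists. The random lists draw genes separately, while these genes move together (estimated correlation of 0.815), so the percentiles do not measure chance. The untransduced level of 1.55 lay inside the MN1 range of 0.04 to 1.98. In 9 genes it lay above every MN1 library and in 2 below every one. The list medians for eosinophil and neutrophil markers were 1.49 and 0.54 above MN1-dpQ, and 7.57 and 3.22 above MN1. The eosinophil value of 1.49 is relative to a mean that includes the low MN1-dpQ replicate 2. Relative to the mean of the transduced libraries, eosinophil markers lay at 4.48 untransduced and at 4.16, 0.30 and 4.32 in MN1-dpQ replicates 1 to 3. The HOXA cluster lay 0.38 below MN1-dpQ and 4.26 below MN1.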

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

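The alternatives were fixed before the data were examined, except the fit without the replicate 2 pair, the list tests that add the block and the side of the untransduced library with the block. Of 102 named genes past the threshold, 0 changed sign under any alternative run. The groups did not overlap in these genes, so refits of the same libraries could hardly turn a sign. With each transduced library left out in turn, 18 of the 102 passed in all 6 fits, among them Cdh3, Krt9, Meis2, Cebpe, Mmp9, Ltf, Ebf1 and Kcna6, and 84 missed in at least 1. Without MN1-dpQ replicate 2 all 102 passed. A gene given above without its leave-out count can be among the 84. Alox15, Adgre1, C1qc, Cd63, Ctsd, Dpf1, Dpf3, Smarcc1, Gar1, Ncl, Fbl and Polr1a, for example, each passed in only 1 of the 6 fits. Library totals alone ended 8 of these calls, for Csf1r and Ctsd and for Rap1b (edgeR Benjamini-Hochberg adjusted p = 0.0709), Hk3 (0.0571), Trp53inp1 (0.0559), Bhlhe40 (0.0543), Ccl9 (0.0525) and Csf2rb2 (0.05002). RLE ended 1, Ctsd (0.0503), leaving out the replicate 2 pair 3, Csf1r (0.0856), Hk3 (0.0689) and Insig1 (0.0520), and the block 2. Limma-voom ended 20 of these calls, the fit with all 7 libraries 7, no filter on low counts 2, and DESeq2 with or without the block 0. Apart from the values given beside the results, the block changed no other call of a named gene in edgeR or of a list in camera at the preset correlation.

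Of 2544 changed genes (901 higher, 1643 lower), the replicate block gave 4545 (2022 higher, 2523 lower), DESeq2 gave 4135 (1813 higher), DESeq2 with the replicate block 5641 (2840 higher, 2801 lower) and the fit without the replicate 2 pair 5247 (2630 higher, 2617 lower). Library totals alone gave 1847 higher. With single libraries left out the count ran from 506 to 6394, with 95 to 3146 higher and 378 to 3248 lower. An adjusted p under 0.01 left 444 genes (99 higher, 345 lower) and an absolute log2 fold change of at least 1 left 1558 (591 higher, 967 lower), by their construction. For the other differences the cause was not tested. Of 2544 calls, 2478 were kept with RLE, 2041 with library totals alone and 2159 with limma-voom, in the same direction.

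Of 29 lists 19 were called. The estimated correlation left 0 with the main fit and 0 with the block. Camera's unadjusted p in the main fit was then 0.0128 for neutrophil markers and 0.0260 for myeloid differentiation transcription factors. Fry called 4 in 1 direction, 4 with the block and 19 in either direction, and these 19 were not the 19 of camera. In either direction fry missed the DNA replication (adjusted p = 0.0999), cholesterol (0.0770), ribosome biogenesis (0.0549), mast cell (0.0887), basophil (0.0579) and megakaryocyte (0.101) lists. It called the p53, glycolysis, erythroid, dendritic, T and NK cell and stromal lists (0.00207 to 0.0397), which camera had not. In 1 direction with the block fry lost the HOXA cluster (adjusted p = 0.0361 to 0.0531) and B lymphoid markers (0.0361 to 0.0674). It gained receptors (0.0739 to 0.0424) and ribosome biogenesis (0.0899 to 0.0424). Other settings gave 15 to 19. Inflammatory genes passed without the replicate 2 pair (adjusted p = 0.0400 in camera), G2/M genes without MN1-dpQ replicate 2 (0.0104) or the pair (0.0240), immediate early and heat shock genes without MN1 replicate 3 (0.0271), and BAF subunits failed with the stricter filter (0.0569). Genes of the untransduced library at least 2-fold from MN1-dpQ ran from 250 to 592 with single libraries left out, against 285. The share of changed genes with the untransduced library nearer MN1-dpQ ran from 91.7% to 98.6% around 95.4%.

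Among genes, reversed signs occurred only in values that had not passed. Mpo turned to 0.57 with the replicate block, 0.0582 with library totals alone, 1.20 without the replicate 2 pair, 0.60 with DESeq2 and the block, 0.54 with limma-voom, and ran from -0.59 to 1.42 with single libraries left out. Zbed6 turned to 0.19 with library totals alone, 0.0157 with DESeq2, 0.0097 with DESeq2 and the block, 0.0014 with limma-voom, and ran from -0.15 to 0.14 with single libraries left out. Hoxb4 turned to 0.053 without the replicate 2 pair. Mecom ran from -0.70 to 0.0519 and Slc7a2 from -1.41 to 0.0388 with single libraries left out. Camera's direction turned for uncalled lists, whose median log2 fold changes were 0.007 with the block and -0.026 to 0.078 with single libraries left out for glycolysis, -0.182 to 0.411 for immediate early and heat shock genes, -0.177 to 0.168 for inflammatory genes, and for T and NK cell markers -0.262 with the block, 0.026 without a filter, 0.108 with the stricter filter, -0.295 without the replicate 2 pair and -0.491 to 0.054 with single libraries left out. The cause was not tested. Depth limits genes near the floor: 3 counts in the untransduced library are 0.0822 CPM.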

Other observations

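The tests in this part were chosen after the results were seen, except the counts over other splits of the libraries. The further genes in this paragraph were chosen after their values were seen. Of the stem cell and leukaemia list, Mllt3 (1.31, SE 0.20) and Lmo2 (1.81, SE 0.46) were higher and Runx1 (-1.49, SE 0.31) lower in MN1. Ceacam1, a cell adhesion gene of granulocytes, stood at 42.9 ± 6.33 CPM in MN1 and 212 ± 3.80 CPM in MN1-dpQ (SD, n = 3 each), and at 209 CPM without transduction. Among interferon-stimulated genes Isg15 (3.28, SE 0.55) and Irf7 (2.76, SE 0.50) were higher in MN1.

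MN1-dpQ replicate 2 lay between the other MN1-dpQ libraries and the MN1 libraries in many changed genes. Across 10340 genes its log2 CPM correlated at 0.951, 0.943 and 0.930 with MN1 replicates 1 to 3. With MN1-dpQ replicates 1 and 3 the values were 0.933 and 0.903, so this measure did not place it with its own group. A mixture with MN1 material needs 1 share for all genes, and genes at least 2-fold higher in MN1 asked for a median share of 0.451 (quartiles 0.240 to 0.650) against 0.738 (0.474 to 0.934) for lower genes, ranges that overlap and did not exclude mixing. After that result was seen the test was rewritten for genes at least 16-fold apart, which asked for 0.161 (0.046 to 0.245) against 0.960 (0.879 to 0.986), and Kcna6 had 0 counts in this library, which argues against mixing only as far as a test changed in this way can and, with an upper quartile of 0.245, against an MN1 library under a wrong label. A culture or day shared by the libraries numbered 2 may account for part, since MN1 replicate 2 lay below MN1 replicates 1 and 3 by a median of -0.992 (quartiles -1.357 to -0.681) in 39 mast cell, basophil and eosinophil markers, against -2.259 in MN1-dpQ. By list, MN1 replicate 2 lay at -1.62 against -0.49 and -0.55 for mast cell markers and at -1.57 against -0.14 and -0.57 for basophil markers. For eosinophil markers it lay at only -3.21 against -2.81 and -2.95, where MN1-dpQ replicate 2 lay at 0.30 against 4.16 and 4.32. No biological explanation was tested, since the design names none within a group. Mn1 also lay toward the MN1 libraries in MN1-dpQ replicate 2. It stood at 404 CPM there, against 691 and 728 CPM in MN1-dpQ replicates 1 and 3 and 287 to 314 CPM in MN1. Whether the Mn1 level has a part in the place of this library was not tested.

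Interferon-stimulated genes lay lower in MN1-dpQ than in MN1 and in the untransduced library. A culture or day shared by libraries of 1 number is balanced over the groups by the design, so it cannot make this difference alone, and the smallest of the 3 pairs' median log2 differences was 0.997 (quartiles 0.593 to 1.576). More monocytes and macrophages in MN1 were argued against by a median log2 fold change of -0.896 (quartiles -1.542 to -0.457) over 26 of their markers. Dendritic cell markers outside the list had a median of 0.454 with quartiles from -0.884 to 0.813, so more dendritic cells in MN1 cannot be told apart from the construct's effect, the genes going both ways. An effect of the construct itself stays open, as does any handling that differed between whole groups.

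Kcna6 was counted at 5.56 to 6.29 CPM in the MN1 libraries and had at most 1 count in any other library. A candidate explanation is that reads of the polyglutamine coding repeat, which MN1-dpQ lacks, were assigned to it: annotated Kcna6 transcripts hold a CAG and CAA run of 54 bases on the strand opposite the transcript, beyond the 31 bases of kallisto's usual k-mer, as do 0.899% of 14683 genes with a run this long on either strand. The longest such run in annotated Mn1 transcripts is 78 bases. The untransduced library had 1225 Mn1 counts and 0 Kcna6 counts, so reads of the endogenous gene gave no Kcna6 counts there. The sequence of the construct and the k-mer used were not analysed here. Of other genes under 1 CPM in MN1-dpQ, 3 of 14 with such a run and 289 of 2582 without were higher in MN1 (two-sided Fisher's exact test, p = 0.203), which decides nothing about them. An induction of Kcna6 by MN1 stays open.

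Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 2544 changed genes, and the highest other gave 0 (edgeR; 20 to 1561 genes at an unadjusted p under 0.05, against 5590). For lists the real split gave 19 calls, as many as only 1 of the 10, and the highest other gave 18. With 10 splits no share under 0.05 can be reached. Each other split puts libraries of both groups on each side, so the group difference widens the spread within the sides. Few gene calls could arise in them, and they do not show what chance would give for genes or lists. The real split parts all 3 same-numbered pairs, as do 3 others, which gave 12 to 18 lists and 0 genes.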
